A study of Mus musculus with 15 samples.

How the data were processed

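RNA was measured in 15 libraries of NIH3T3 cells in 5 groups of 3 biological replicates: the empty vector, EGFR WT, EGFR Del1, EGFR L858R and EGFR L861Q. Per the labels the libraries were poly-A selected and dUTP strand-specific. The deposited table holds raw counts of reads per Ensembl gene, which the authors made with TopHat2 2.1.0 and HTSeq 0.6.0 on mm10. The strand setting, the annotation and any filter were not stated. Each of the 15 columns was mapped to 1 sample by its name, and the closing entries for reads without a gene were kept apart from the gene counts.

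Gene counts per library were 370955 to 812517, and uniquely placed reads were 11794996 to 25215856. Features were annotated with GENCODE vM21 on the same build, which held a model for 48435 of 48795. A partner was the opposite-strand gene that shared at least 50 exon bases with a feature and held at least 0.8 of the overlapped bases. Partner counts were summed over the features that share a partner. A partner was named, and counted in lists, only where its features were not protein coding or its mean count reached 48.3, the 99.5th percentile of protein-coding features without an overlap. All partners past the count filter were tested and enter the counts of calls, also those left unnamed by this rule. The partner reading was chosen after the data were examined, as was everything said to be so below.

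Differences were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr with its minimum count of 10 and total of 15) in a model of the 5 groups over all 15 samples. A gene passed at an adjusted p (Benjamini-Hochberg) below 0.05. Each mutant and EGFR WT were compared with the vector, each mutant with EGFR WT and with each other mutant, and the mean of the 3 mutants with EGFR WT. Replicate numbers were not treated as pairs, since 10 of 30 correlations between residuals of the same number exceeded 0.1 (-0.454 to 0.302). Those between EGFR WT and EGFR Del1 all exceeded it (0.190, 0.242 and 0.211), and a replicate block was run as an alternative. Lists of genes, 46 in all, were written before the data were examined, and those with at least 3 measured genes (27 for features, 19 for partner genes) were tested with camera in limma 3.58.1 at a preset correlation of 0.01. An estimated correlation was the alternative. R 4.3.3 and Python 3.11.15 were used.

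The genes named for a comparison were the 10 with the largest change each way among those past the threshold (5 each way between mutants and for their mean). They had a mean of at least 5 CPM in the higher group, no overlap between the groups' replicates and a symbol that is not a predicted or clone name. Members of the fixed lists and Egfr were named besides. For 3 libraries against 3, chance leaves 10% of genes without overlap. For partner genes this rule was applied after the data were examined, and features named beside them were chosen after their values were seen. CPM values are counts scaled to the TMM-adjusted total of the library, over all features or all partner genes.

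On simulated data with 200 genes changed at the depth and spread of EGFR L858R and the vector, edgeR recovered 11.9, 53.2 and 88.7% of features changed 1.5, 2 and 4-fold, with 6 false calls. For partner genes it recovered 30.2, 62.3 and 98.4%, with 8 false calls. Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no filter, at least 10 counts in 3 samples, DESeq2 1.42.0, limma-voom, a replicate block, a minimum change of 2-fold, the 2 groups alone and leaving out each library. Added later were unique reads as library size, leaving out the 2 libraries rich in a ribosomal RNA feature, leaving out classes of features, and the partner counts. Correlations and covariances of fold changes and counts of shared calls were compared with those in 50 simulations of unchanged groups that share 1 vector group. Each run drew all 15 libraries, the vector included, from the fitted vector means, with each gene drawn independently.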

Results

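RNA from 5 lines of NIH3T3, a mouse fibroblast cell line, was sequenced after poly-A selection, with 3 biological replicates per line and 15 libraries in all. The lines stably carried the empty vector pBABEpuro (the vector line), the wild-type epidermal growth factor receptor (EGFR WT), or the receptor mutants EGFR Del1, EGFR L858R and EGFR L861Q. The stated purpose of the series was to compare the mutant lines with the empty vector line. The labels do not say whether the replicates of a construct were cultures of 1 line or separately made lines. In the former case each difference below holds the construct together with whatever else differed between the lines, and the replicates measure the spread between cultures alone. The deposited table gave 370955 to 812517 counts on genes per library (median 596806), which was 2.29 to 2.85% of all reads. Of all reads, 70.4 to 75.0% overlapped no counted feature. The p-values and errors of the comparisons rest on a spread estimated per gene over all 15 libraries, with n = 3 per line unless stated. They do not measure the spread of the 2 compared lines alone, and that spread differed between lines. Between 2 libraries of a line, chi-square per degree of freedom was 1.41 to 2.28 in EGFR WT and 5.47 to 15.5 in EGFR Del1.

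The counts lay mostly where a gene overlaps another on the opposite strand. The libraries were strand-specific per the extract protocol, and features that share exon bases with an opposite-strand gene held 91.3% of gene counts although they were 8503 of 48795 features. Abundant fibroblast genes without such an overlap held few counts, with means per library of 37.4 for Actb, 30.6 for Vim and 18.7 for Col1a1. The mitochondrial mt-Nd6, the 1 coding gene on the minus strand of the mitochondrial genome among 13, had a mean of 38712 counts, against at most 2827 for any of the others. The counts of a feature were therefore also read as those of its partner, the opposite-strand gene that covers most of the overlap, a reading adopted after the data were examined. Counts of 2436 partner genes passed the count filter, and the names below are partner genes unless a feature is named as such. Numbers of partner genes that passed a test are over all 2436, also those that the rules for names leave out. Of the exons of a partner gene, only the overlapping part can be seen. Partner counts are the whole counts of the features, so reads outside the shared exon bases are included.

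**Figure D1:**
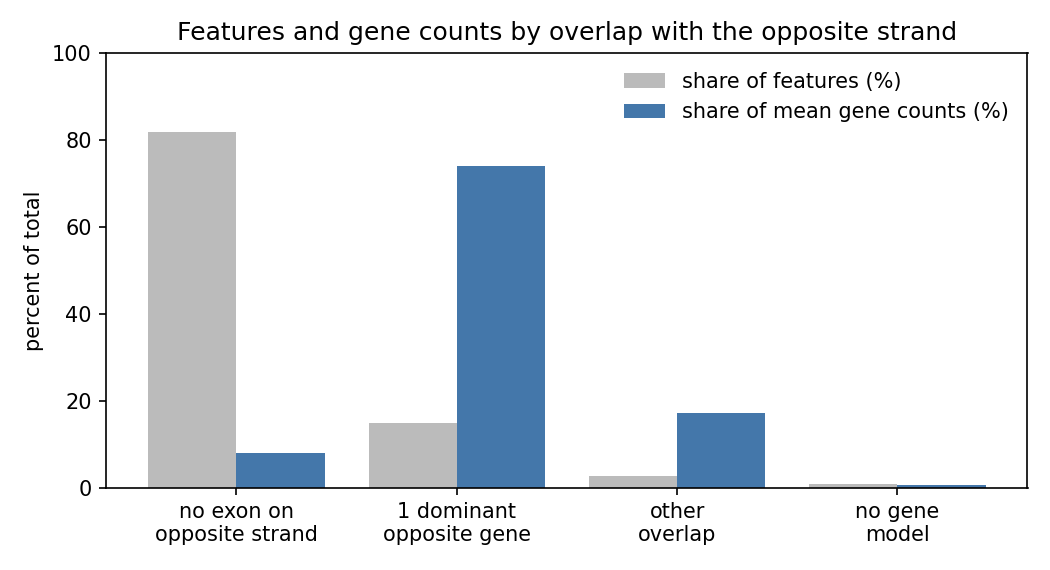
Bars show the percent of the 48795 features (grey) and of the mean gene counts (blue) in 4 classes of overlap with exons on the opposite strand. Features without an opposite-strand exon were 81.8% of features and held 8.04% of counts, while those with 1 dominant opposite gene were 14.8% of features and held 74.0% of counts.

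Positions on mm10 of the genes reported most often were taken from the annotation. It placed Ccnd1 (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925) with 1100 exon bases inside the feature LTO1. It placed Hmga2 (ENSMUSG00000056758, chromosome 10, 120361275 to 120476469) with 140 exon bases inside the feature 1700006J14Rik, and Rgs16 (ENSMUSG00000026475, chromosome 1, 153740349 to 153745468) with 236 exon bases inside the feature Gm28513. It also placed Sfrp2 (ENSMUSG00000027996, chromosome 3, 83766321 to 83774316) with 347 exon bases inside the feature Gm26771, Thbs1 (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133) with 208 exon bases inside the feature Gm29233, and Sned1 (ENSMUSG00000047793, chromosome 1, 93235841 to 93301065) with 1855 exon bases inside the feature Mterf4.

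The endogenous Egfr gene could not be read. Its feature held 0 to 5 counts per library in all 15 libraries, with a mean of 2.45 CPM (counts scaled to the library total), and it has no exon on the opposite strand. A count of 0 allows up to 3 counts, which was 3.69 to 8.09 CPM at the depths of these libraries and covers counting error only. Without a count filter no comparison of Egfr against the vector or EGFR WT passed in edgeR, where the lowest adjusted p was 0.482. The introduced receptors could not be measured from this table.

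Whether any of the 5 lines differed was asked first. In a test over all 5 lines, 557 of 2436 partner genes and 947 of 4290 features had an adjusted p below 0.05. The first component of the feature levels held 36.2% of their variance. It placed the vector and EGFR WT libraries between -26.9 and -19.3, and the EGFR L858R and EGFR L861Q libraries between 9.65 and 32.2. The EGFR Del1 libraries spread on it, with replicates 1, 2 and 3 at -13.1, 15.3 and 3.63. They lay at -17.2, 18.4 and -1.27 on an axis within the mutant lines that is weighed further below. That axis followed measures of the libraries, among them the share of reads placed at several genome sites. How much of the first component is such a difference between libraries was not tested. The share of reads placed at several genome sites also differed between lines, with means of 22.5 ± 0.204% (SD) in the vector line, 24.2 ± 0.121% in EGFR WT, 24.3 ± 1.09% in EGFR Del1, 25.7 ± 1.08% in EGFR L858R and 26.7 ± 0.540% in EGFR L861Q.

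EGFR WT against the vector line asked what accompanied the unmutated receptor. Hmga2, which encodes a chromatin architectural protein, rose from 405 ± 63.9 to 1576 ± 121 CPM (mean ± SD; log2 fold change 1.96 ± 0.19 (SE), adjusted p = 2.30e-06). Ccnd1, which encodes the cell cycle regulator cyclin D1, rose from 599 ± 31.3 to 1140.4 ± 24.7 CPM (log2 fold change 0.93 ± 0.11, adjusted p = 2.93e-05). Sned1 fell from 15585 ± 1626 to 3169.9 ± 193 CPM (log2 fold change -2.30 ± 0.14, adjusted p = 1.33e-08), and the cytochrome P450 gene Cyp2f2 fell from 441 ± 10.2 to 26.1 ± 12.4 CPM (log2 fold change -4.06 ± 0.31, adjusted p = 2.12e-07). The laminin gene Lamc3 went from 80.6 to 0.665 CPM (adjusted p = 2.33e-05). Ank2 went from 33.4 to 6.55 CPM (adjusted p = 0.0122), and the neurotrophin gene Bdnf from 2.1 to 22.8 CPM (adjusted p = 0.00463). Lamc3, Ank2 and Bdnf had means of at most 3 counts per library in the lower line, so the size of their changes is imprecise. Among other genes with the largest changes, Ccbe1, Rbm38, Pole, Coq10b, Bach2, Mtus1, E2f7 and Bhlhe41 rose, with log2 fold changes of 1.40 to 1.89. Ace, Gdpd2, Arhgap20, Ptchd1, Fam13a and Glt8d2 fell, with log2 fold changes of -2.33 to -1.91. With 1 library left out, calls were lost for Ccbe1 (without vector replicate 1 or 2 or EGFR WT replicate 2, adjusted p up to 0.0810) and Coq10b (without vector replicate 1 or 3 or EGFR WT replicate 1 or 2 or 3, adjusted p up to 0.173). Fam13a (without vector replicate 2 or EGFR WT replicate 1 or 2 or 3, adjusted p up to 0.0723) lost theirs likewise. Calls of Coq10b (with a replicate block or unique reads as library size) and Fam13a (with limma-voom) in EGFR WT were lost too.

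Gene lists fixed before the data were examined were tested against all other partner genes with camera. Of 5 measured mitosis genes, 4 rose (4 adjusted over the list alone), among them Prc1 at log2 fold change 1.15 ± 0.10 (list test, adjusted p = 0.000442). Of 4 DNA replication genes, 2 rose (4 adjusted over the list alone), namely Mcm7 at 1.09 ± 0.34 and Fen1 at 0.81 ± 0.11 (list test, adjusted p = 0.00409). Of 4 actin and contractile genes, 3 rose (3 adjusted over the list alone), Vcl at 0.44 ± 0.10, Zyx at 0.70 ± 0.18 and Tpm4 at 0.57 ± 0.13 (list test, adjusted p = 0.00409). All 3 ribosome biogenesis genes rose (3 adjusted over the list alone), Pes1 at 0.59, Polr1a at 0.57 and Tsr1 at 0.54 (list test, adjusted p = 0.00409). Of 4 genes of ERK output and feedback, 2 rose (2 adjusted over the list alone), Hmga2 and Ccnd1 (list test, adjusted p = 0.00904). Phlda1 had a log2 fold change of 0.18 and the ERK pathway inhibitor Spry1 one of -0.30, neither past the threshold. Of 6 growth factor genes, 3 rose (4 up and 1 down adjusted over the list alone), Bdnf, Pdgfc at 1.10 and Ccn2 at 1.09 (list test, adjusted p = 0.0416, and adjusted p = 0.178 with an estimated correlation), a call lost without vector replicate 1, where the adjusted p was 0.0691. With 1 library left out, calls were lost for Mcm7 (without any 1 of the 6 libraries, adjusted p up to 0.145) and Vcl (without vector replicate 2 or 3, adjusted p up to 0.0557). Zyx (without vector replicate 1 or 2 or EGFR WT replicate 3, adjusted p up to 0.0938) and Polr1a (without any 1 of the 6 libraries, adjusted p up to 0.166) lost theirs likewise. Calls of Mcm7 (with limma-voom, a replicate block or unique reads as library size) and Polr1a (with no count filter, a replicate block or unique reads as library size) in EGFR WT were lost too.

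For EGFR WT against the vector, 279 of 2436 partner genes passed (138 up, 141 down), 108 of them at least 2-fold. Of the 4290 features taken as deposited, 335 passed (177 up, 158 down). Among the features, Mterf4, whose partner is Sned1, had a log2 fold change of -2.25 and Bach2os, with partner Bach2, one of 1.59, while Postn, a matrix gene without a partner, went from 22.2 to 1.02 CPM. At the depths of the EGFR WT libraries 3 counts were 4.74 to 5.18 CPM, so the size of the change of Postn is imprecise. The count of partner genes was 171 without vector replicate 1, 164 without vector replicate 2, 182 without vector replicate 3, 157 without EGFR WT replicate 1, 167 without EGFR WT replicate 2 and 153 without EGFR WT replicate 3, and 624 in a fit to these 6 libraries alone.

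EGFR Del1 against the vector line asked which genes differed with this mutant. Ccnd1 rose from 599 ± 31.3 to 5240.4 ± 472 CPM (log2 fold change 3.13 ± 0.12, adjusted p = 2.61e-12) and Hmga2 to 4844 ± 1070.2 CPM (log2 fold change 3.58 ± 0.19, adjusted p = 6.48e-10). Rgs16, a regulator of G protein signalling, rose from 36.7 ± 7.36 to 496 ± 18.7 CPM (log2 fold change 3.72 ± 0.15, adjusted p = 1.0e-11). Sfrp2, a secreted modulator of Wnt signalling, fell from 5199.7 ± 74.9 to 325 ± 55.9 CPM (log2 fold change -4.00 ± 0.15, adjusted p = 2.61e-12), and the matrix glycoprotein gene Thbs1 from 960.2 ± 19.3 to 123 ± 35.1 CPM (log2 fold change -2.95 ± 0.18, adjusted p = 2.76e-09). Tcim, Ereg, Lrrc8d and Ccbe1 also rose, with log2 fold changes of 2.67 to 4.37, where Ereg encodes epiregulin, a ligand of EGFR. Cyp2f2, the cadherin gene Fat4, Ltbp2, Arhgap20, Aplf and P3h2 fell, with log2 fold changes of -3.54 to -2.93. Rtp3, Plxna4 and Bdnf, which had vector means of 2.50, 3.63 and 2.1 CPM, reached 63.5, 57.4 and 27.7 CPM. Lamc3 and Ank2 fell to 1.43 and 0.708 CPM. Ereg, Lrrc8d, Rtp3, Plxna4, Bdnf, Lamc3 and Ank2 had means of at most 3 counts per library in the lower line, so their changes are imprecise. In this comparison 391 of 2436 partner genes passed (193 up, 198 down), 206 of them at least 2-fold. Taken as deposited, 506 of 4290 features passed (260 up, 246 down). Among the features, LTO1 with partner Ccnd1 had a log2 fold change of 3.12 and Ankmy1 with partner Gpc1 one of 2.52.

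EGFR L858R against the vector line asked the same of the L858R mutant. Ccnd1 rose to 5496 ± 384 CPM (log2 fold change 3.20 ± 0.12, adjusted p = 2.87e-12), Hmga2 to 5841 ± 909 CPM (log2 fold change 3.85 ± 0.20, adjusted p = 2.38e-10) and Rgs16 to 774 ± 13.9 CPM (log2 fold change 4.36 ± 0.15, adjusted p = 2.69e-12). Sfrp2 fell to 392 ± 35.7 CPM (log2 fold change -3.72 ± 0.14, adjusted p = 4.86e-12) and Thbs1 to 88.1 ± 18.2 CPM (log2 fold change -3.45 ± 0.19, adjusted p = 6.85e-10). Tcim, Lrrc8d, Ereg and the Wnt pathway transcription factor gene Lef1 rose, with log2 fold changes of 2.60 to 4.27. Cyp2f2, Ltbp2, P3h2, Rtl1, Fat4, Sp140 and Aplf fell, with log2 fold changes of -4.05 to -2.76. Rtp3, Plxna4 and Bdnf reached 47.1, 33.7 and 31.7 CPM from the vector means given above, and Lamc3 fell to 3.65 CPM. Lrrc8d, Lef1, Ereg, Rtl1, Sp140, Rtp3, Plxna4, Bdnf and Lamc3 had means of at most 3 counts per library in the lower line. Their changes are therefore imprecise. In this comparison 546 of 2436 partner genes passed (277 up, 269 down), 286 of them at least 2-fold. Of the 4290 features taken as deposited, 844 passed (462 up, 382 down). Of 1260 tested features without an opposite-strand exon, 163 rose and 55 fell.

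EGFR L861Q against the vector line asked the same of the third mutant. Ccnd1 rose to 4389 ± 452 CPM (log2 fold change 2.87 ± 0.12, adjusted p = 1.14e-11), Hmga2 to 4404 ± 863 CPM (log2 fold change 3.44 ± 0.19, adjusted p = 1.13e-09) and Rgs16 to 643 ± 38.7 CPM (log2 fold change 4.09 ± 0.15, adjusted p = 7.52e-12). Sfrp2 fell to 473 ± 75.5 CPM (log2 fold change -3.47 ± 0.14, adjusted p = 1.14e-11), and Thbs1 fell to 166 ± 24.2 CPM (log2 fold change -2.52 ± 0.17, adjusted p = 1.71e-08). Tcim, Ccbe1, Ereg and Tulp2 rose, with log2 fold changes of 2.11 to 3.67. Cyp2f2, Sp140, P3h2, Rtl1, Ltbp2, Arhgap20 and Ace fell, with log2 fold changes of -3.61 to -2.58. Rtp3, Plxna4 and Bdnf reached 37.8, 40.8 and 28.8 CPM, and Lamc3 and Ank2 fell to 1.05 and 1.30 CPM. Ereg, Sp140, Rtl1, Rtp3, Plxna4, Bdnf, Lamc3 and Ank2 had means of at most 3 counts per library in the lower line. Their changes are therefore imprecise. In this comparison 521 of 2436 partner genes passed (260 up, 261 down), 279 of them at least 2-fold. Taken as deposited, 894 of 4290 features passed (523 up, 371 down). Of 1260 tested features without an opposite-strand exon, 244 rose and 46 fell.

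The lists showed which groups moved in the mutant lines against the vector, in the order EGFR Del1, EGFR L858R and EGFR L861Q. In each mutant line 3 of 4 measured genes of ERK output and feedback rose and 1 fell (the same counts adjusted over the list alone). Hmga2, Ccnd1 and Phlda1 rose, Phlda1 with log2 fold changes of 1.37, 1.11 and 1.18. Spry1, which encodes an inhibitor of this pathway, went against the direction of the list and fell, with log2 fold changes of -1.78, -2.26 and -2.12. The list tests gave adjusted p = 0.000481, 0.00220 and 0.00173, the second of which became adjusted p = 0.0639 with an estimated correlation. All 4 DNA replication genes rose in each mutant line (4 adjusted over the list alone), Fen1 with log2 fold changes of 1.07, 1.12 and 1.07 and Ccne2 with 1.58, 1.90 and 1.38. The list passed in each (adjusted p = 0.00389, 0.00384 and 0.00356, with adjusted p = 0.0639 for EGFR L858R with an estimated correlation). In edgeR Mcm7 had adjusted p = 0.0486, 0.0438 and 0.0144, and Gins2 had adjusted p = 0.0386, 0.0174 and 0.0168. Calls of Mcm7 and Gins2 in the mutant lines were not followed through the settings. Of 5 mitosis genes, 3, 4 and 4 rose (5, 4 and 5 adjusted over the list alone), Prc1 with log2 fold changes of 1.32, 1.43 and 1.30 (adjusted p = 0.000481, 0.00220 and 0.00144, with adjusted p = 0.0663 for EGFR L858R with an estimated correlation). In EGFR Del1, with 1 library left out, calls were lost for Spry1 (without vector replicate 2 or 3 or EGFR Del1 replicate 2, adjusted p up to 0.109). Ccne2 (without vector replicate 2, adjusted p up to 0.0570) lost theirs likewise. The call of Spry1 in EGFR Del1 was lost with a replicate block or the 2 groups alone. In EGFR L858R, with 1 library left out the call of Spry1 (without EGFR L858R replicate 3, adjusted p up to 0.0529) was lost. In EGFR L861Q, with 1 library left out, calls were lost for Spry1 (without EGFR L861Q replicate 1, adjusted p up to 0.0518). Ccne2 (without vector replicate 2 or 3 or EGFR L861Q replicate 1 or 3, adjusted p up to 0.0902) lost theirs likewise.

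Groups that fell against the vector were matrix and antigen presentation genes. Of 5 matrix genes, Thbs1, Col5a1 and Fbn1 fell in each mutant line (3 down adjusted over the list alone), Fbn1 with log2 fold changes of -1.18, -1.29 and -0.87 and Col5a1 with -0.70, -0.86 and -0.51. The tenascin gene Tnc rose in EGFR L861Q, with a log2 fold change of 0.57 (1 up adjusted over the list alone). The matrix list passed in EGFR Del1 (adjusted p = 0.0109, and adjusted p = 0.112 with an estimated correlation) and in EGFR L858R (adjusted p = 0.00277, and adjusted p = 0.0672 with an estimated correlation). It had an adjusted p of 0.0636 in EGFR L861Q. The antigen presentation genes Tapbp, Tap2 and H2-Q4 all fell in EGFR Del1 and EGFR L858R (3 adjusted over the list alone in each), and Tapbp and Tap2 fell in EGFR L861Q (2 adjusted over the list alone). This list passed in EGFR Del1 (adjusted p = 0.0109, and adjusted p = 0.221 with an estimated correlation) and EGFR L858R (adjusted p = 0.0175, and adjusted p = 0.276 with an estimated correlation). Its adjusted p was 0.0636 in EGFR L861Q. Of 3 cholesterol genes, Dhcr24 and Lss rose in each mutant line (3, 2 and 2 adjusted over the list alone), Dhcr24 with log2 fold changes of 0.89, 0.91 and 0.96 and Lss with 0.50, 0.47 and 0.51. Dhcr24 rose in EGFR WT too, at 0.67. This list passed in EGFR Del1 alone (adjusted p = 0.0149, and adjusted p = 0.0810 with an estimated correlation), with adjusted p = 0.0610 in EGFR L858R and 0.0636 in EGFR L861Q. In EGFR L858R, with 1 library left out the call of Lss (without vector replicate 1 or EGFR L858R replicate 2 or 3, adjusted p up to 0.108) was lost. The call of Lss in EGFR L858R was lost with no count filter or unique reads as library size. In EGFR Del1, with 1 library left out, calls were lost for Lss (without vector replicate 1 or EGFR Del1 replicate 3, adjusted p up to 0.106). H2-Q4 (without vector replicate 2 or EGFR Del1 replicate 2 or 3, adjusted p up to 0.115) lost theirs likewise. Calls of Lss (with no count filter, unique reads as library size or the 2 groups alone) and H2-Q4 (with no count filter, DESeq2 or the 2 groups alone) in EGFR Del1 were lost too. In EGFR L861Q, with 1 library left out, calls were lost for Col5a1 (without vector replicate 2 or 3 or EGFR L861Q replicate 1 or 3, adjusted p up to 0.0978). Lss (without vector replicate 1, adjusted p up to 0.0798) lost theirs likewise. Calls of Col5a1 (with upper-quartile scaling or unique reads as library size) and Lss (with no count filter or unique reads as library size) in EGFR L861Q were lost too.

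**Figure D2:**
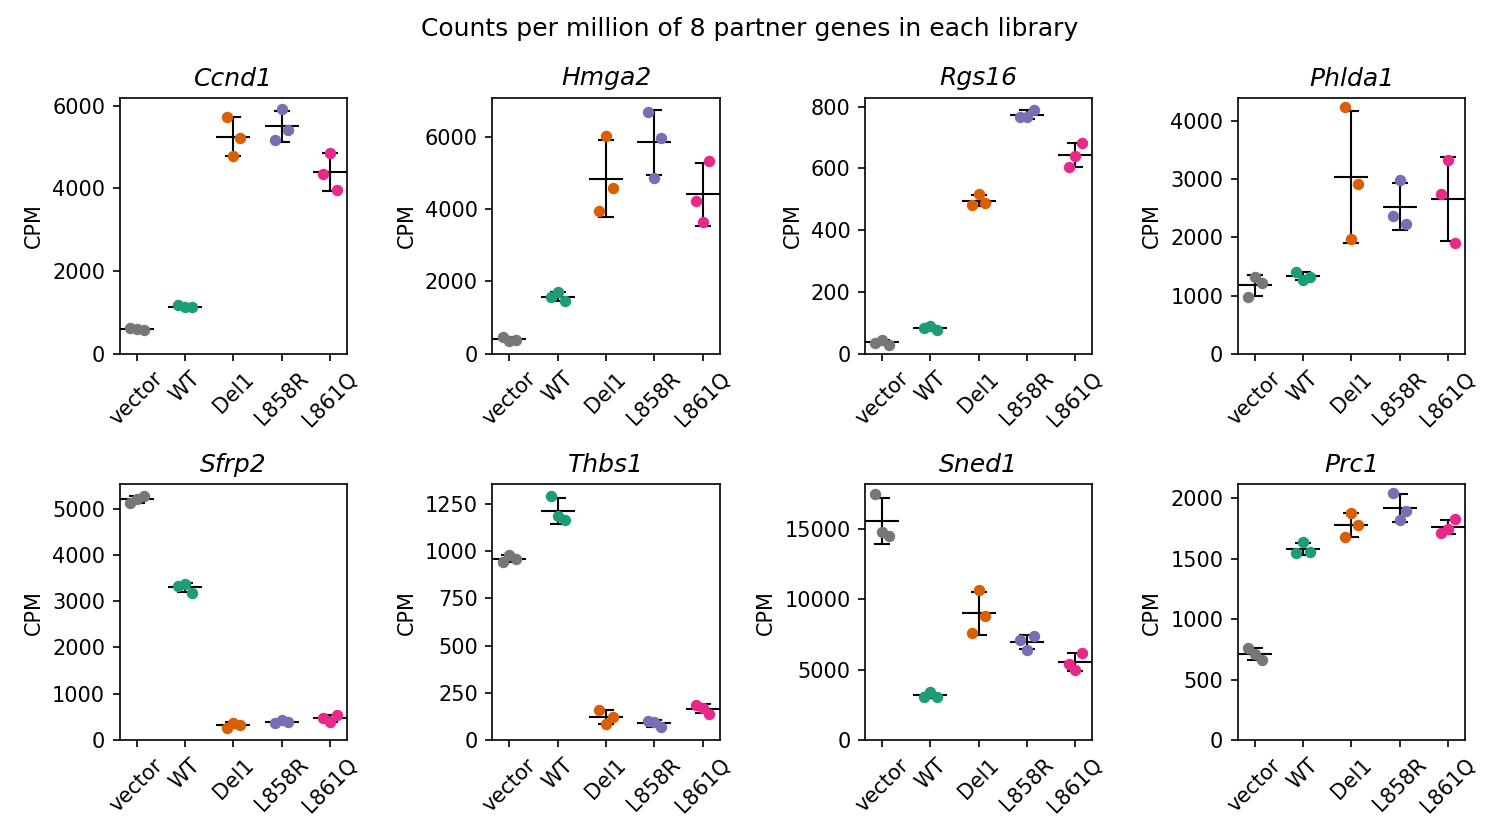
Each panel shows 1 partner gene in CPM (vertical axis, from 0) for each of the 5 lines, with a point per library and a bar for the mean and its SD over 3 libraries. Ccnd1 lies at 599 CPM in the vector line, 1140.4 in EGFR WT and 5240.4, 5496 and 4389 in the mutant lines, while Thbs1 lies at 960.2, 1214, 123, 88.1 and 166 CPM in the same order.

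EGFR Del1 against EGFR WT asked what set the mutant line apart from the line with the unmutated receptor. Ccnd1 was higher at 5240.4 ± 472 against 1140.4 ± 24.7 CPM (log2 fold change 2.20 ± 0.11, adjusted p = 5.85e-10), and so was Has2, a hyaluronan synthase gene, at 1384 ± 337 against 262 ± 26.6 CPM (log2 fold change 2.40 ± 0.20, adjusted p = 1.75e-07). Thbs1 was lower at 123 ± 35.1 against 1214 ± 68.7 CPM (log2 fold change -3.29 ± 0.18, adjusted p = 9.05e-10), as was Sfrp2 at 325 ± 55.9 against 3297 ± 97.9 CPM (log2 fold change -3.35 ± 0.14, adjusted p = 7.12e-11). Tcim, Rgs16, the ceruloplasmin gene Cp, Ereg, Ankrd44 and Fam13a were higher, with log2 fold changes of 2.19 to 3.81. Igsf10, Ltbp2, Cdc42ep3, Fam198b, Mtus1, Fat4, Bach2 and Ccn2, which encodes connective tissue growth factor, were lower, with log2 fold changes of -2.47 to -1.85. Rtp3 and Plxna4 were at 63.5 and 57.4 CPM, against 2.87 and 2.79 CPM in EGFR WT, where they had means of at most 3 counts per library. In this comparison 173 of 2436 partner genes passed (87 up, 86 down), 95 of them at least 2-fold. Of the 4290 features taken as deposited, 210 passed (105 up, 105 down). Partner genes that passed numbered 115 without EGFR Del1 replicate 3. With 1 library left out the call of Fam13a (without EGFR WT replicate 2 or EGFR Del1 replicate 2, adjusted p up to 0.0666) was lost. The call of Fam13a in EGFR Del1 was lost with limma-voom.

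EGFR L858R against EGFR WT showed Ccnd1 higher at 5496 ± 384 against 1140.4 ± 24.7 CPM (log2 fold change 2.27 ± 0.11, adjusted p = 2.36e-10), and the metallothionein gene Mt2 higher at 4609 ± 360.3 against 927 ± 69.0 CPM (log2 fold change 2.31 ± 0.17, adjusted p = 5.98e-08). Thbs1 was lower at 88.1 ± 18.2 CPM (log2 fold change -3.79 ± 0.19, adjusted p = 2.36e-10) and Sfrp2 at 392 ± 35.7 CPM (log2 fold change -3.06 ± 0.14, adjusted p = 1.24e-10). Tcim, Rgs16, Fam13a, Cp, Has2 and Ankrd44 were higher, with log2 fold changes of 2.23 to 3.70, and Rtp3 and Plxna4 were at 47.1 and 33.7 CPM. Cd55, Cdc42ep3, Fam198b, Ltbp2, Igsf10, Mtus1, Rtl1 and Ccn2 were lower, with log2 fold changes of -3.19 to -2.1. In this comparison 275 of 2436 partner genes passed (137 up, 138 down), 157 of them at least 2-fold. Taken as deposited, 520 of 4290 features passed (309 up, 211 down). Partner genes whose features hold a run of T and C or of G and A were 27 of the 275, and 95 of all 2436 tested. Partner genes that passed numbered 162 without EGFR WT replicate 1, 183 without EGFR WT replicate 3 and 181 without EGFR L858R replicate 1, and 414 without a count filter. Features without an opposite-strand exon gave 159 of the 309 that rose and 19 of the 211 that fell, and the count over features with such an exon alone was 320. Rtl1, Rtp3 and Plxna4 had means of at most 3 counts per library in the lower line, so their changes are imprecise. With 1 library left out the call of Rtl1 (without EGFR WT replicate 1 or EGFR L858R replicate 3, adjusted p up to 0.0763) was lost.

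EGFR L861Q against EGFR WT showed Ccnd1 higher at 4389 ± 452 CPM (log2 fold change 1.94 ± 0.11, adjusted p = 2.52e-09) and Zfp704 higher at 711 ± 90.0 against 166 ± 8.94 CPM (log2 fold change 2.09 ± 0.16, adjusted p = 1.46e-07). Thbs1 was lower at 166 ± 24.2 CPM (log2 fold change -2.86 ± 0.17, adjusted p = 4.96e-09) and Sfrp2 at 473 ± 75.5 CPM (log2 fold change -2.81 ± 0.14, adjusted p = 3.69e-10). Tcim, Rgs16, Cp, Fam13a, Tulp2 and Ereg were higher, with log2 fold changes of 1.92 to 3.11, and Rtp3 and Plxna4 were at 37.8 and 40.8 CPM. Sp140, Rtl1, P3h2, Ltbp2, Fam198b, Cdc42ep3, Igsf10 and Plpp1 were lower, with log2 fold changes of -2.34 to -1.72. In this comparison 212 of 2436 partner genes passed (120 up, 92 down), 124 of them at least 2-fold. Of the 4290 features taken as deposited, 472 passed (313 up, 159 down). Features with a run of T and C or of G and A gave 28 of the 212 partner genes, against 10 of 173 in EGFR Del1. Partner genes that passed numbered 129 without EGFR WT replicate 1, 140 without EGFR WT replicate 2, 138 without EGFR WT replicate 3 and 138 without EGFR L861Q replicate 1. Features without an opposite-strand exon gave 196 of the 313 that rose and 7 of the 159 that fell, and the count over features with such an exon alone was 230. Sp140, Rtl1, Rtp3 and Plxna4 had means of at most 3 counts per library in the lower line, so their changes are imprecise. With 1 library left out, calls were lost for Fam13a (without EGFR WT replicate 1 or 2 or 3 or EGFR L861Q replicate 1 or 3, adjusted p up to 0.0732) and Tulp2 (without EGFR WT replicate 1 or 3, adjusted p up to 0.0708). Rtl1 (without EGFR WT replicate 1 or EGFR L861Q replicate 1, adjusted p up to 0.0715) lost theirs likewise. The call of Fam13a in EGFR L861Q was lost with limma-voom.

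Against EGFR WT, the lists that moved in all 3 mutant lines with either correlation were ERK output and feedback, matrix, and actin and contractile genes, given in the order EGFR Del1, EGFR L858R and EGFR L861Q. Of 4 genes of ERK output and feedback, 3 rose in each line, with 0, 1 and 0 falling (3 up and 1 down adjusted over the list alone in each). Phlda1 had log2 fold changes of 1.19, 0.93 and 1.0, and Hmga2 of 1.62, 1.89 and 1.48. Spry1 had log2 fold changes of -1.48, -1.96 and -1.82, of which the value in EGFR L858R passed (list tests, adjusted p = 0.000156, 0.00141 and 0.00111). Its own adjusted p was 0.139 in EGFR Del1 and 0.0588 in EGFR L861Q. Among the settings and left-out libraries, Spry1 passed in 1 fit for EGFR Del1 and in 4 for EGFR L861Q. Of 5 matrix genes, Col5a1, Fbn1, Tnc and Thbs1 fell in each line (4, 4 and 5 down adjusted over the list alone), Tnc with log2 fold changes of -1.16, -1.21 and -0.51 (list tests, adjusted p = 1.32e-06, 4.08e-07 and 3.63e-06). Of 4 actin and contractile genes, 3, 3 and 2 fell (3, 3 and 2 adjusted over the list alone), the vinculin gene Vcl with log2 fold changes of -0.88, -0.67 and -0.90 and Smtn with -0.79, -0.72 and -0.73 (list tests, adjusted p = 0.000156, 0.00513 and 0.00255). This list had risen in EGFR WT against the vector. Against the vector, Smtn fell in each mutant line (edgeR, adjusted p = 0.0350, 0.0499 and 0.0475). Vcl fell in EGFR Del1 and EGFR L861Q and did not pass in EGFR L858R. Zyx passed in no mutant line against the vector, and Tpm4 rose in each, with log2 fold changes of 0.39, 0.59 and 0.50. These calls against the vector were not followed through the settings. In EGFR Del1, with 1 library left out the call of Smtn (without EGFR Del1 replicate 3, adjusted p up to 0.0583) was lost. The call of Col5a1 in EGFR Del1 was lost with unique reads as library size. In EGFR L858R, with 1 library left out, calls were lost for Phlda1 (without EGFR WT replicate 2 or 3, adjusted p up to 0.0573) and Spry1 (without EGFR WT replicate 1 or 2 or 3 or EGFR L858R replicate 1 or 3, adjusted p up to 0.154). Smtn (without EGFR WT replicate 1 or EGFR L858R replicate 1 or 3, adjusted p up to 0.0703) lost theirs likewise. Calls of Phlda1 (with unique reads as library size) and Spry1 (with limma-voom, a replicate block or unique reads as library size) in EGFR L858R were lost too. In EGFR L861Q, with 1 library left out, calls were lost for Tnc (without EGFR WT replicate 1 or 2 or EGFR L861Q replicate 1, adjusted p up to 0.0911) and Smtn (without EGFR WT replicate 1 or EGFR L861Q replicate 1 or 3, adjusted p up to 0.0631). Col5a1 (without any 1 of the 6 libraries, adjusted p up to 0.156) lost theirs likewise. Calls of Smtn (with unique reads as library size) and Col5a1 (with upper-quartile scaling, a replicate block or unique reads as library size) in EGFR L861Q were lost too.

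Other lists passed against EGFR WT with the preset correlation and not with an estimated one. Of 4 TGF-beta targets, Ltbp2 and Ltbp3, both of the latent TGF-beta binding protein family, fell in each mutant line (2, 3 and 3 adjusted over the list alone), Ltbp3 with log2 fold changes of -0.76, -0.91 and -0.66 (list tests, adjusted p = 0.00365, 0.00429 and 0.00255, and adjusted p = 0.106, 0.0953 and 0.0861 with an estimated correlation). In EGFR Del1, 1 of 3 epithelial-mesenchymal transition factors rose (2 adjusted over the list alone), Zeb2 at a log2 fold change of 2.1 (list test, adjusted p = 0.0421, and adjusted p = 0.107 with an estimated correlation). That call was lost without EGFR WT replicate 2 and without EGFR Del1 replicate 1, where the adjusted p reached 0.105. Zeb2 passed in EGFR L858R too, at 1.54, and not in EGFR L861Q, at 0.95. Zeb2 had means of 43.8, 16.1, 71.0, 45.2 and 32.0 CPM in the vector, EGFR WT, EGFR Del1, EGFR L858R and EGFR L861Q. It fell in EGFR WT against the vector (log2 fold change -1.46, adjusted p = 0.0174) and passed in no mutant line against the vector. In EGFR L858R, 1 of 4 oxidative phosphorylation genes fell (2 adjusted over the list alone), Ndufa9 at -0.82 (list test, adjusted p = 0.0303, and adjusted p = 0.0953 with an estimated correlation). This call was lost without EGFR WT replicate 3 and without EGFR L858R replicate 2, with an adjusted p of up to 0.0662. Ndufa9 passed in EGFR Del1 too, at -0.57, and not in EGFR L861Q, at -0.52. In EGFR L861Q its adjusted p was 0.0588, and it passed in 3 of the fits with other settings or a left-out library. Of 3 fibroblast markers, Fbn1 fell in EGFR L858R and in EGFR L861Q (2 and 2 adjusted over the list alone), while Fn1 and Pdgfra did not pass (list tests, adjusted p = 0.0303 and 0.0373, and adjusted p = 0.282 and 0.283 with an estimated correlation). These calls were lost without EGFR L858R replicate 2, with an adjusted p of 0.0571, and without EGFR L861Q replicate 3, with an adjusted p of 0.102. No list of markers of another cell type had 3 measured partner genes. In EGFR L858R, with 1 library left out the call of Zeb2 (without EGFR WT replicate 1 or 2 or EGFR L858R replicate 2 or 3, adjusted p up to 0.0705) was lost. In EGFR Del1, with 1 library left out the call of Ndufa9 (without any 1 of the 6 libraries, adjusted p up to 0.165) was lost. The call of Ndufa9 in EGFR Del1 was lost with upper-quartile scaling, no count filter, a replicate block, unique reads as library size or the 2 groups alone. In EGFR L861Q, with 1 library left out the call of Ltbp3 (without EGFR WT replicate 1, adjusted p up to 0.0840) was lost. The call of Ltbp3 in EGFR L861Q was lost with unique reads as library size.

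The mean of the 3 mutant lines against EGFR WT asked how the mutants differed from it on average, a difference that single lines can carry. Tcim, Rgs16 and Cp were the genes with the largest rises besides Rtp3 and Plxna4, with log2 fold changes of 3.54 ± 0.24, 2.89 ± 0.12 and 2.71 ± 0.31. Thbs1, Sfrp2, Cdc42ep3, Ltbp2 and Fam198b fell most, with log2 fold changes of -3.31 ± 0.12, -3.07 ± 0.10, -2.35 ± 0.31, -2.31 ± 0.18 and -2.25 ± 0.12. In this comparison 323 of 2436 partner genes passed (162 up, 161 down), 139 of them at least 2-fold. Taken as deposited, 578 of 4290 features passed (306 up, 272 down). With unique reads as library size 344 of 539 features were up, or 63.8% against 52.9%. The lists called were ERK output and feedback (3 up and 1 down, adjusted over the list alone 3 and 1, adjusted p = 0.00137), matrix (4 of 5 down, 4 adjusted over the list alone, adjusted p = 6.01e-07), actin and contractile genes (3 of 4 down, 3 adjusted over the list alone, adjusted p = 0.00137) and TGF-beta targets (3 of 4 down, 3 adjusted over the list alone, adjusted p = 0.00168, and adjusted p = 0.0780 with an estimated correlation). Oxidative phosphorylation (1 of 4 down, 1 adjusted over the list alone, adjusted p = 0.0387, and adjusted p = 0.111 with an estimated correlation) and fibroblast markers (1 of 3 down, 2 adjusted over the list alone, adjusted p = 0.0332, and adjusted p = 0.277 with an estimated correlation) passed too, the former not without EGFR WT replicate 3, where its adjusted p was 0.107. The count of partner genes was 189 without EGFR WT replicate 1, 207 without EGFR WT replicate 2 and 207 without EGFR WT replicate 3, and the count over features with an opposite-strand exon alone was 367.

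Comparisons between mutant lines asked whether the mutants differed from each other. EGFR L861Q and EGFR Del1 differed in 25 partner genes (22 up and 3 down in EGFR L861Q), of which 9 rest on features with a run of T and C or of G and A, against 95 of 2436 tested. Of the 25, 21 changed at least 2-fold, but of the 5 genes named next only Fat4 and H19 did. How many of the 25 meet the rules for names is not given. Fat4 was higher in EGFR L861Q at 337 ± 29.1 against 156 ± 12.8 CPM (log2 fold change 1.12 ± 0.13, adjusted p = 0.000257), Tnc at 1152 ± 29.6 against 731 ± 95.4 CPM (0.66 ± 0.13, adjusted p = 0.0144) and the mitochondrial DNA polymerase gene Polg at 769.6 ± 48.1 against 485 ± 75.6 CPM (0.67 ± 0.13, adjusted p = 0.0144). The imprinted noncoding RNA gene H19 was lower at 69.9 ± 17.6 against 161 ± 13.5 CPM (log2 fold change -1.16 ± 0.18, adjusted p = 0.00249), as was Sned1 at 5526 ± 633 against 9027 ± 1529.9 CPM (-0.71 ± 0.13, adjusted p = 0.0104). Of 4290 features 125 differed (117 up, 8 down), of which 87 up and 2 down had no opposite-strand exon, and the count over features with such an exon alone was 25. The count of partner genes was 14 without EGFR Del1 replicate 1, 11 without EGFR Del1 replicate 3 and 10 without EGFR L861Q replicate 1, 2 in a fit to these 6 libraries alone, where none of these 5 genes passed, and 50 without a count filter. With 1 library left out, calls were lost for Tnc (without EGFR Del1 replicate 1 or 3 or EGFR L861Q replicate 1, adjusted p up to 0.110) and Polg (without EGFR Del1 replicate 1 or 3 or EGFR L861Q replicate 1 or 3, adjusted p up to 0.106). Sned1 (without EGFR L861Q replicate 1, adjusted p up to 0.0796) lost theirs likewise.

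EGFR L858R and EGFR Del1 differed in 0 partner genes in edgeR, where 159 had an unadjusted p below 0.05, and in 8 with DESeq2 and 1 with limma-voom. The count of partner genes was highest in edgeR with no count filter, as given in the section on processing. Of 4290 features 25 differed, 24 of them higher in EGFR L858R and 18 of those without an opposite-strand exon, such as Slitrk4 at 66.0 against 5.21 CPM, and the count was 0 over features with such an exon alone. Of those 18 features, 16 hold a run of T and C and 2 hold neither kind of run. The count of features was also 0 without features that hold a run, with limma-voom or in the 2 groups alone. It was 2 with a replicate block, and higher with no count filter or DESeq2. The count of partner genes was 8 without EGFR Del1 replicate 2 and 17 without EGFR L858R replicate 2, and that of features was 0 without EGFR Del1 replicate 1, 44 without EGFR Del1 replicate 2, 0 without EGFR Del1 replicate 3, 1 without EGFR L858R replicate 1, 124 without EGFR L858R replicate 2 and 1 without EGFR L858R replicate 3. EGFR L861Q and EGFR L858R differed in 0 partner genes in edgeR, where 151 had an unadjusted p below 0.05, in 4 with DESeq2 and in 0 with limma-voom. For partner genes the count was again highest with no count filter. These 2 lines differed in 7 features, all higher in EGFR L861Q, among them Tmco1, Nrp2 and Xkrx, with log2 fold changes of 1.36, 1.25 and 1.23, a count that was 3 without EGFR L858R replicate 1, 0 without EGFR L858R replicate 3, 1 without EGFR L861Q replicate 1 and 2 without EGFR L861Q replicate 2, while that of partner genes was 1 without EGFR L861Q replicate 2 and 1 without EGFR L861Q replicate 3. The matrix list was higher in EGFR L861Q than in EGFR L858R (adjusted p = 0.000231, and adjusted p = 0.0781 with an estimated correlation), with 0 of 5 genes past the threshold and 2 adjusted over the list alone, and Tnc at 1152 ± 29.6 against 707 ± 99.7 CPM. Secreted proteases and inhibitors were lower (adjusted p = 0.0340, and adjusted p = 0.139 with an estimated correlation), with 0 of 3 genes past the threshold and 0 adjusted over the list alone. That call was lost without EGFR L858R replicate 1 or 3 and without EGFR L861Q replicate 1 or 2, with an adjusted p of up to 0.128.

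Calls shared by the lines against the same vector libraries were then counted. In all 4 EGFR lines 75 partner genes were higher and 78 lower than in the vector line. Independent calls would give 0.133 and 0.136, and simulated groups without any change gave 0 each way with a shared simulated vector group (mean of 50 runs). Those runs hold no changed genes, so how many calls the shared libraries add among changed genes stays open. They also draw each gene independently, whereas 1 axis held 45.6% of the within-group variance of the mutant libraries. Calls that such joint variation adds are therefore not covered either. Among the genes higher in all 4 lines, Hmga2 had log2 fold changes of 1.96 to 3.85, the cell cycle transcription factor gene E2f7 of 1.43 to 2.01, Pole, which encodes a DNA polymerase subunit, of 1.65 to 2.06, and the glypican gene Gpc1 of 1.19 to 2.51. Rbm38, Bhlhe41, Rtkn2, Ccbe1, Bdnf and Rgs16 were also higher in all 4. Among the genes lower in all 4 lines, Cyp2f2 had log2 fold changes of -4.06 to -3.46, Fat4 of -3.50 to -1.60, and Nid2, a basement membrane gene, of -2.09 to -1.46, with Lamc3, Ank2, Arhgap20, Aplf, Ace, Ajm1 and Wnk4 beside them. All 3 mutant lines shared 146 higher and 155 lower partner genes, against 2.34 each way from independent calls. For features the counts were 94 higher and 86 lower in all 4 lines, and 190 higher and 202 lower in all 3 mutant lines. In EGFR WT, with 1 library left out, calls were lost for Rtkn2 (without EGFR WT replicate 1, adjusted p up to 0.0596). Gpc1 (without vector replicate 1 or 3 or EGFR WT replicate 3, adjusted p up to 0.0763) lost theirs likewise.

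Across partner genes, the fold changes against the vector had a correlation of 0.898 between EGFR L858R and EGFR L861Q, 0.851 between EGFR Del1 and EGFR L858R and 0.817 between EGFR Del1 and EGFR L861Q. Between EGFR WT and the mutant lines it was 0.627 for EGFR Del1, 0.522 for EGFR L858R and 0.573 for EGFR L861Q. Genes are not independent replicates, and a shared vector group alone gave correlations of 0.472 to 0.494 in the simulated data. Across features, EGFR WT had correlations of 0.584 with EGFR Del1, 0.415 with EGFR L858R and 0.427 with EGFR L861Q, where the simulated data gave 0.492, 0.478 and 0.499. Changes of single lines, which the simulated data lack, lower a correlation, so these are not compared. The covariances were 0.266, 0.227 and 0.232 across features, against 0.0896, 0.0891 and 0.0900 in the simulated data, and 0.275, 0.253 and 0.266 across partner genes, against 0.0639, 0.0646 and 0.0641. No partner gene was called in opposite directions in 2 mutant lines, while 8, 8 and 5 were called in opposite directions in EGFR WT and in EGFR Del1, EGFR L858R and EGFR L861Q.

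**Figure D3:**
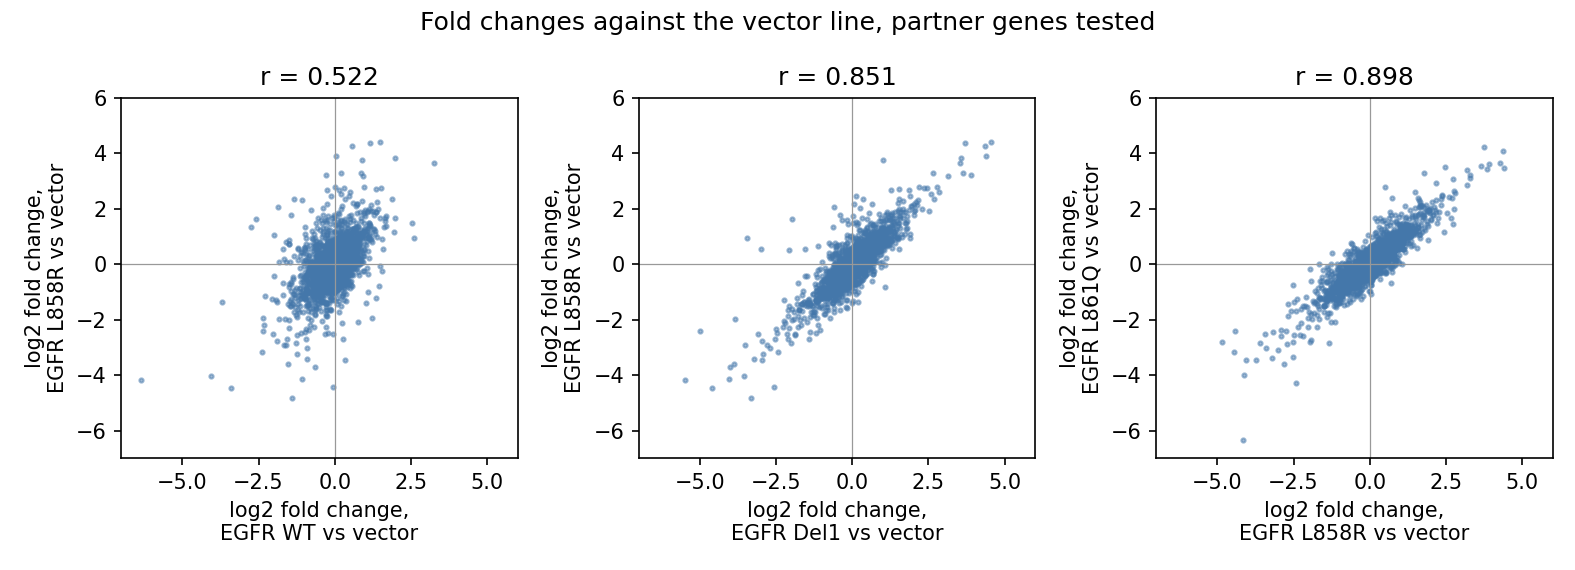
Each point is a partner gene, of 2436 tested, with its log2 fold change against the vector line in 1 EGFR line (horizontal axis) and in another (vertical axis). The correlation across genes was 0.522 for EGFR WT and EGFR L858R, 0.851 for EGFR Del1 and EGFR L858R, and 0.898 for EGFR L858R and EGFR L861Q, which includes the part that the shared vector libraries add.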

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

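The tests of the counting strand, of runs of T and C, of a leak for features without a run and of a receptor effect were chosen after their results were seen, and partner counts were added after the data were examined. Some changes of EGFR WT against the vector went back in the mutant lines. Of the partner genes higher in EGFR WT than in the vector, 27 were lower in the mean of the 3 mutants than in EGFR WT, where independent calls would give 9.12. Of those lower in EGFR WT, 31 were higher in the mutants, where 9.38 would be given. EGFR WT libraries enter both comparisons, which by itself favours opposite directions. Simulated groups without any change gave means of 0 and 0.02 such genes, but those runs hold no changed genes and draw each gene independently. How many that sharing adds among changed genes therefore stays open. Genes that moved further the same way numbered 16 up and 24 down, with 9.18 and 9.32 from independent calls. Tnc, a matrix gene, had means of 777, 1636, 731, 707 and 1152 CPM in the vector, EGFR WT, EGFR Del1, EGFR L858R and EGFR L861Q, and Ccn2 had means of 303, 648, 179.8, 149.9 and 202 CPM. EGFR L861Q and EGFR Del1 differed in 25 partner genes by a direct test, of which 9 rest on features with a run of T and C or of G and A. That count was 14 without EGFR Del1 replicate 1, 11 without EGFR Del1 replicate 3, 10 without EGFR L861Q replicate 1 and 2 in a fit to the 6 libraries alone, and another split of the libraries called 181.

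Reads placed at several sites are outside the gene counts. Their share was higher in every EGFR line than in the vector line, at 24.2% in EGFR WT, 24.3% in EGFR Del1, 25.7% in EGFR L858R and 26.7% in EGFR L861Q, against 22.5%.

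The first pattern weighed was that abundant genes held few counts. None (0 of 6) of Actb, Eef1a1, Rpl3, Tubb5, Vim and Col1a1 was among the 100 highest features, which argues against counts taken without regard to strand at low depth. Features with an opposite-strand exon held 91.3% of gene counts, as counts taken on the strand opposite to the transcripts need. No biological explanation was tested, since every line showed the pattern.

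The second pattern was a rise of features without an opposite-strand exon in EGFR L858R and EGFR L861Q against EGFR WT. With scaling from this class alone, 70.3% and 71.8% of calls were still up, which argues against a higher strand leak as the whole cause, while without features that hold a run it was 53% and 56.8%. Scaling on the class tends to balance that share by itself, so a leak for those features stays open. Features with a run of alternating T and C rose by 1.35 and 1.60 (log2) more than those with neither run. Features with a run of G and A only had medians of 1.08 and 1.37, against 0.30 and 0.38 with neither run, and 23 and 22 of 52 were up. The features 4-fold up in both lines shared a 25-base word more often than random sets (permutation p = 0.0001, the smallest 10000 sets can give), so reads placed on runs of either kind may explain part of the rise. Words of higher complexity were not shared more often (permutation p = 0.994). An effect of the receptor mutation cannot be told apart from other differences between the groups, with 1 group per receptor and no label that says whether its replicates are separately made lines.

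The third pattern was that libraries of the mutant lines part along 1 axis within their groups, which held 45.6% of the within-group variance of partner genes. Transcript length followed it with rho = 0.0124, within the bound set beforehand as speaking against a length bias. Length and GC content here are those of the longest transcript of the partner gene, of whose exons only the overlapping part is seen. A length bias over that part therefore stays open. GC content followed it with rho = -0.332, and gene counts per library had r = -0.702, rho = -0.650, exact permutation p = 0.0463 and r = -0.862 without the 2 libraries at its ends (9 libraries, within groups). The mt-Nd6 level followed it with r = 0.955, rho = 0.967, exact permutation p = 0.00926 and r = 0.929 without the 2 libraries at its ends. For the level of other features without an opposite-strand exon r was 0.924, rho = 0.917, exact permutation p = 0.0231 and r = 0.856 without the 2 libraries at its ends. The share of reads at several sites had r = 0.884, rho = 0.817, exact permutation p = 0.0139 and r = 0.785 without the 2 libraries at its ends, the level on T and C runs r = 0.837, rho = 0.817, exact permutation p = 0.00926 and r = 0.791 without the 2 libraries at its ends, and the share of CT010467.1 r = -0.735, rho = -0.867, exact permutation p = 0.00463 and r = -0.829 without the 2 libraries at its ends. GC bias and depth remain candidate explanations, and differences in the composition or quality of the RNA, which these measures could reflect, were not tested apart. Culture conditions of single replicates are not given and were not tested.

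Other splits of the samples showed whether regrouped libraries give as many calls. For any difference among the 5 lines, 1 of 100 splits (the real one) called as many features (947, highest other 15) or partner genes (557, highest other 22). No other split drawn came near the real count, and 1 in 100 is the smallest share these splits can give. The splits cannot separate the receptor from anything else that differed between the lines. For the mean of the mutants against EGFR WT, 1 of 100 splits called as many features (578, highest other 560) and 2 of 100 as many partner genes (323, highest other 467), so a split that calls more points to a structure of the samples. For 3 libraries against 3, 10 splits are too few for a share under 0.05. The 4 lines against the vector called 335, 506, 844 and 894 features and 279, 391, 546 and 521 partner genes, and the mutants against EGFR WT 210, 520 and 472 features and 173, 275 and 212 partner genes, in the order used above, with a highest other of 0 in each and 1 split as large. EGFR L861Q against EGFR Del1 called 125 features (highest other 19, 1 split as large) and 25 partner genes (highest other 181, 3 splits). EGFR L858R against EGFR Del1 called 25 features (highest other 504, 2 splits) and 0 partner genes (highest other 356, 10 splits). EGFR L861Q against EGFR L858R called 7 features (highest other 60, 2 splits) and 0 partner genes (highest other 87, 10 splits). In these last comparisons splits that call several times the real count point to a structure within the groups, as on the axis above.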

How the results depend on the processing

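Partner counts, unique reads as library size and the settings that leave out classes of features or the 2 libraries rich in ribosomal RNA were chosen after the data were examined. No list and no partner gene named for a comparison reversed in the settings run for it, and features named singly were not followed through the settings. Of 297 named gene comparisons, 291 passed, of which 24 were lost in at least 1 setting and 37 without at least 1 library. Of those that did not pass, 3 passed in at least 1 of these fits.

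Requiring at least 2-fold lowered counts by construction. Features gave 155, 300, 538 and 572 for EGFR WT, EGFR Del1, EGFR L858R and EGFR L861Q against the vector, 129 and 343 for EGFR Del1 and EGFR L858R against EGFR WT, and 309 for the mean of the mutants. Partner genes gave 108, 206, 286 and 279 against the vector, 95, 157 and 124 against EGFR WT and 139 for the mean. Shared calls fell to 35 up and 54 down (features) and 18 and 37 (partner genes) in all 4 lines, and to 97, 115, 68 and 77 in the 3 mutant lines.

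For the other moved counts the cause was not tested. EGFR L858R against EGFR Del1 (25 features) gave 91 with no filter, 50 with DESeq2, 0 with limma-voom, 2 with a replicate block, 0 with only the 2 groups, 123 without the 2 libraries rich in ribosomal RNA, and 0 with features with an opposite-strand exon only or without features that hold a run. Its partner count (0) was 2 with RLE size factors and upper quartile, 35 with no filter, 8 with DESeq2, 1 with limma-voom and with unique reads, and 11 without the 2 libraries. EGFR L861Q against EGFR L858R (7 features) gave 13 with no filter and with DESeq2, 11 with unique reads, and 0 with only the 2 groups or with an opposite-strand exon only. Its partner count (0) was 1 with upper quartile and with unique reads, 9 with no filter and 4 with DESeq2. EGFR L861Q against EGFR Del1 gave 25 features with an opposite-strand exon only and 43 without runs, and 50 partner genes with no filter and 2 with only the 2 groups. EGFR WT against the vector gave 792 features and 624 partner genes with only the 2 groups. Features with an opposite-strand exon only gave 320 for EGFR L858R and 230 for EGFR L861Q against EGFR WT, and 367 for the mean. No filter gave 414 partner genes for EGFR L858R against EGFR WT. With an estimated correlation 0 of 28 list calls for features and 23 of 44 for partner genes passed. With a replicate block 23 of 24 counts stayed within 1.5 times.

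Leaving out 1 library moved features from 191 to 214 (EGFR WT against the vector), 121 to 288, 270 to 699 and 283 to 564 (the mutants against EGFR WT), 265 to 857 (their mean), 0 to 124 (EGFR L858R against EGFR Del1), 65 to 137 (EGFR L861Q against EGFR Del1) and 0 to 10 (EGFR L861Q against EGFR L858R). Partner genes, in that order, ranged from 153 to 182, 115 to 233, 162 to 395, 129 to 226, 189 to 428, 0 to 17, 10 to 29 and 0 to 1. List calls for features ranged from 18 (without EGFR L861Q replicate 1) to 44 (without EGFR L858R replicate 3). Counts for any difference and for the mutants against the vector stayed within 1.5 times. With unique reads the share of calls that were up went from 52.8 to 40.9% for features in EGFR WT against the vector, from 66.3 to 80.2% in EGFR L861Q against EGFR WT, from 52.9 to 63.8% for the mean of the mutants against EGFR WT, and from 50.7 to 40.2% for partner genes in EGFR L858R against the vector. In the last case the median log2 fold change of all partner genes was -0.10, against 0.0155 in the main fit. At this depth, genes changed 1.5-fold were mostly missed in simulated data.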

Other observations

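Some single members of the fixed lists with fewer than 3 measured genes, or outside the called lists, are given as means in the vector, EGFR WT, EGFR Del1, EGFR L858R and EGFR L861Q. Txnip, a gene repressed by AKT signalling through FOXO factors, had means of 3171, 3731, 1535, 1440.3 and 1476 CPM. The EGFR family ligand gene Nrg1 had 219, 182, 63.1, 60.9 and 84.4 CPM, and the adhesion gene Vcam1 had 524, 274, 92.1, 102 and 107 CPM. The hypoxia target Bnip3 had 1110.4, 1698, 3127, 5103 and 3161 CPM, and Wnt5a had 35.4, 41.5, 137, 154 and 149 CPM. All 5 of these passed in each mutant line against the vector, with log2 fold changes of -2.51 to 1.96 in EGFR Del1, -2.35 to 2.20 in EGFR L858R and -2.28 to 2.07 in EGFR L861Q. Other measured members of the lists of Txnip and Bnip3 did not pass against the vector in any mutant line: Irs2 had 62.7, 70.7, 58.7, 48.4 and 39.8 CPM, and the hypoxia targets Ndrg1 and Mxi1 had 1116, 1105, 982, 935 and 1051 and 269, 301, 280.3, 304 and 279 CPM. Lrig1, of the EGFR negative feedback list, had 56.8, 104, 169, 185 and 156 CPM. The immediate early gene Jun had 431, 682, 1000, 722 and 936 CPM. Both genes passed in each mutant line against the vector. Tnk2, of the list of Lrig1, had 178, 340, 188, 235 and 260 CPM and passed in EGFR L861Q alone of the mutant lines. Ereg, of the list of Nrg1, had 6.50, 9.12, 47.5, 38.5 and 36.1 CPM and rose in each mutant line. Lrig1, Jun and Tnk2 were not followed through the settings.

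A ribosomal RNA feature, CT010467.1, held 20.6% of gene counts in vector replicate 1 (95% Wilson interval 20.5 to 20.7%, which covers counting error only) and 8.24% in EGFR L858R replicate 2 (8.18 to 8.31%). Features without an opposite-strand exon that hold a T and C run had 2008 ± 262 CPM (SD) in the vector line, 1748 ± 89.5 in EGFR WT, 2121 ± 672 in EGFR Del1, 6309 ± 2806 in EGFR L858R and 7234 ± 1372 in EGFR L861Q.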
